A study of Drosophila melanogaster with 2 samples.

How the data were processed

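ChIP-seq peak lists were analysed for 2 biological replicates of 0 to 24 h embryos expressing sens-2-eGFP, precipitated with an anti-GFP antibody after sonication to fragments of 200 to 800 bp, per the labels. The replicate numbers were taken from the labels. The 8 deposited lists gave peaks on dm6, per the labels and the text files deposited with the samples. The aligner, the peak caller and their versions are not given in the sources used here. Per the text files deposited with the samples, each replicate had a ranked and a thresholded list made from its own alignments, and the series had 2 ranked lists and 2 thresholded lists made from the alignments of both replicates, so peaks were called both per sample and across samples. The conservative thresholded list was the main list.

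In every list the authors gave a signal value per peak, on the scale of that list, and a whole-number score made from the irreproducible discovery rate (IDR). The deposited ranked lists also gave −log10 of the global IDR. The deposited score equalled 125 × log2 of the inverse IDR, limited to 1000, within 1 unit for all 144164 ranked peaks of the list that compared the replicates, and the lowest score in the thresholded lists was 830, an IDR of 0.01. Signal and score are the authors' own values per peak and were compared within a list, with few exceptions. These were the Spearman and Pearson correlations between replicates and the median signal of ranked peaks that the conservative list lacks. Signal columns that carry the values of single replicates without naming them were not used, and the signal given for a replicate comes from that replicate's own list. The thresholded lists derived from a further file whose content is not described in the sources used here. Read depth per library is unknown, so intervals of shares cover counting of peaks only, and neighbouring peaks are not independent.

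Peaks on chromosomes 2L, 2R, 3L, 3R, 4, X and Y were used, and 16 of the 2899 peaks of the main list on unplaced scaffolds were left out of every result. Peak edges are given 1-based. Genes came from Ensembl release 115 (BDGP 6.54), without transposable elements and pseudogenes, and sequence from Release 6 of the genome, which shares the coordinates of dm6. A summit counted as promoter within 500 bp of a transcript start, and otherwise as 5' UTR, coding sequence, 3' UTR, intron or intergenic in that order, with exons of non-coding genes counted as introns. A gene's domain was its body with 2 kb upstream, and a summit in overlapping domains counted for each gene. For 5 list members, the symbol of the annotation was used in place of an older one.

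Replicate lists were compared by overlap of at least 1 bp, with exact binomial intervals at 95% and 1000 circular shifts within chromosomes. Peaks were paired by nearest summit in both directions for Spearman and Pearson correlation, with 100000 random pairings. Positions were tested against 1000 circular shifts (two-sided), X density with an exact binomial test, and 15 gene lists against 10000 random lists matched on decile of domain length (two-sided, Benjamini-Hochberg over the lists). Motifs were counted on either strand in the 101 bp around the summit and in a window of the same width 300 bp away, upstream for odd and downstream for even peaks, and tested with the exact McNemar test, with Benjamini-Hochberg adjustment over 14 preset motifs or all hexamers, with reverse complements merged. Each peak kept its flank when a subset was taken. Median signal with and without AAATCA was compared over 100000 relabellings.

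Tests, lists, motifs and alternatives were fixed before the data were examined, except where stated. That each peak keeps its flank in subsets was set afterwards, as were 4 further alternatives: without peaks of signal under 20, only peaks of full width (296 bp), without peaks at the sens-2 domain, and the flank on the other side. The named genes were those nearest to the 15 strongest peaks, up to 3 members per list with the strongest peak in their domain, sens, sens-2 and the E(spl) complex members, and the 5 genes with most summits. Alternatives were the other thresholded list, each replicate's own list, the stronger peaks of the list by signal, 6 chromosomes without Y, other overlap rules, promoter windows of 250 and 1000 bp, other rules for assigning summits to genes, windows of 51 and 201 bp, flanks 1000 bp away, peaks away from promoters, and ranked peaks below the threshold as comparison.

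The tests were also checked on simulated data. Of 100 sets of 2883 random summits, 1 passed the promoter test, 5 the AAATCA test and 4 the X test at 0.05, and all 100 sets with 4.99% of summits moved to transcript starts or to AAATCA sites passed the matching test. Of 100 random lists of 23 genes, 2 passed the list test, and 92 of 100 lists in which about 50% of genes had a summit passed. The random summits were placed without regard to sequence, so summit and flank had the same base composition on average, and the random lists held scattered genes. The check therefore does not show how the motif tests behave at AT-rich summits, or the list test for genes that lie side by side. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.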

Results

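Binding of the Senseless-2 protein was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos collected from 0 to 24 h. Senseless-2, encoded by sens-2, is a zinc-finger transcription factor and the paralog of Senseless, a regulator of sensory organ development. The embryos carried a sens-2 fusion to eGFP, and the chromatin was precipitated with an antibody against GFP. The 2 samples formed 1 group of 2 biological replicates, so that the replicates could be compared with each other and the shared peaks with the genome. No other condition and no input or mock library was analysed here. Replicate 1 had 1990 thresholded peaks and replicate 2 had 1643, and the conservative list across both replicates had 2899, of which 2883 lay on chromosomes 2L, 2R, 3L, 3R, X and Y of dm6. Read depth per library is unknown from peak lists, and signal values belong to the authors' own scale of each list, so no standard deviation between replicates is given for single peaks.

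The strongest peaks lay mainly at gene starts. The highest signal, 1085, was at X 2703761 to 2704024, with its summit 43 bp from the start of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. CG14100 (FBgn0036889, 3L 19590498 to 19590753) followed with a signal of 1043 and px, the wing vein gene plexus (FBgn0003175, 2R 22514182 to 22514422), with 963. Among the 15 strongest peaks the nearest starts also belonged to CG11050, CenG1A, Art3, Tcs5, ph-p, CG7601, eEF1gamma, CG18549, mRpL41, CG13323, PNPase and CG1888, with signals from 812 down to 645. The summit named for CG11050 was intronic and that for CG13323 lay in intergenic sequence 11915 bp away. The summit named for eEF1gamma (3R 29214324 to 29214567) was 5733 bp from it, at the start of another annotated transcript, and eEF1gamma had a promoter summit of its own with a signal of 302. The Ugalt peak had the highest signal in each replicate's own list as well, 688 in replicate 1 and 403 in replicate 2.

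The tagged gene itself held a cluster of peaks. The domain of sens-2 (FBgn0051632, 2L 6821934 to 6838995, with 2 kb upstream) contained 8 summits, of which 6 were intronic and 2 at the promoter. The strongest, at 6833752 to 6833958 in an intron, had a signal of 466 and rank 34 in the list, and the promoter summits had signals of 305 and 257. Each replicate's own thresholded list had 6 summits in the domain. The domain of sens (FBgn0002573, 3L 13396228 to 13401125) held 0 summits. Ranked peaks below the threshold had a median signal of 28.2 in the 60 kb centred on the gene, against a median of 16.1 over all such windows of the genome, a comparison chosen after the locus was seen. Extra copies of the region in the tagged line would raise the signal of peaks here as well, and could not be told apart from binding.

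**Figure D1:**
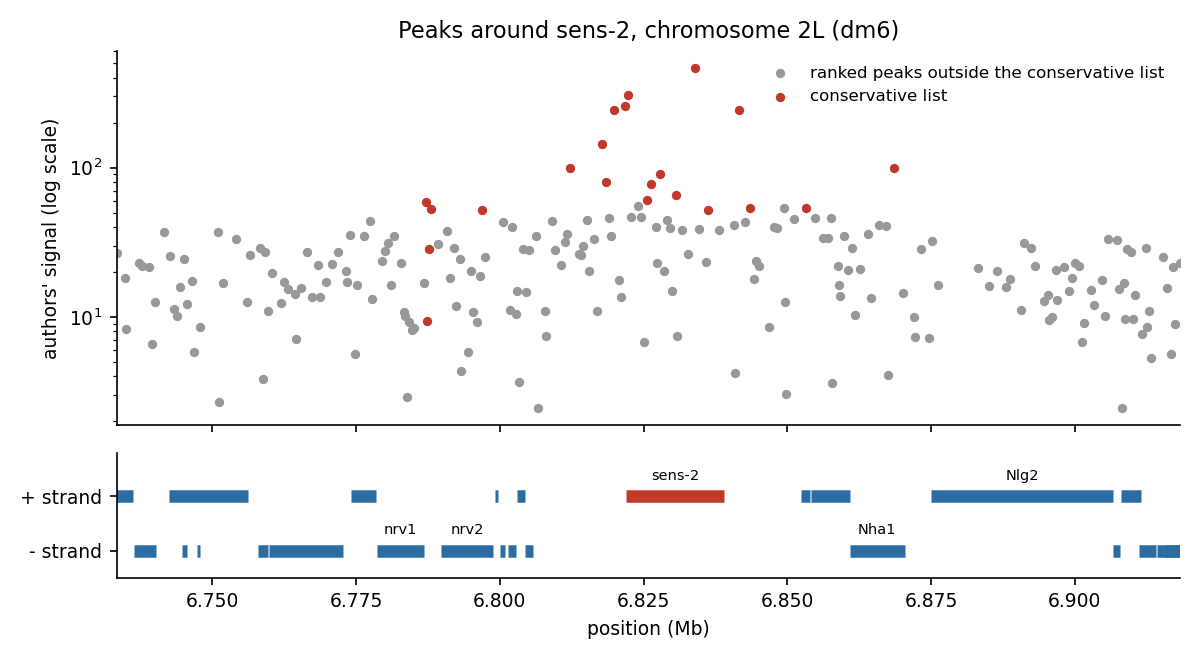
Peaks around sens-2 on chromosome 2L, with position in Mb on the horizontal axis and the authors' signal per peak on a log axis; red points are peaks of the conservative list and grey points other ranked peaks, with genes drawn below by strand. The 8 summits in the sens-2 domain reach a signal of 466.

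The most summits lay in the domains of kirre, a cell adhesion gene of myoblast fusion that spans 394 kb, CG1677 and sbb, with 13 each. Raf, a kinase of the MAP kinase pathway, and ush, a partner of GATA factors, had 9 each. The strongest of these peaks was at sbb, with a signal of 368 in an intron (2R 18338418 to 18338584). In all, 2500 of 13968 protein-coding genes (17.9%) had a summit in their domain.

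The replicates shared nearly all of their strongest peaks and fewer of their weak ones. Of the replicate 1 peaks on assembled chromosomes, 1167 of 1960 (59.5%, exact binomial 95% interval 57.3 to 61.7) overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks 1162 of 1636 did (71.0%, 68.8 to 73.2). Circular shifts of 1 list gave mean shares of 0.619% and 0.747%, and none of 1000 shifts reached the observed share (one-sided permutation p = 0.001, the smallest the shifts allow). With each list divided by signal into 4 classes of equal size, 96.7% of the 490 strongest replicate 1 peaks were shared, against 23.9% of the 490 weakest, and in replicate 2 98.5% of the 409 strongest and 35.7% of the 409 weakest. In the other replicate's ranked list, 98.2% of the replicate 1 thresholded peaks and 96.1% of those of replicate 2 had an overlapping peak. The ranked lists are long, with 117153 peaks in replicate 1 and 93828 in replicate 2, and the share under shifts was not computed. Of the conservative list, 867 peaks (30.1%) overlapped no thresholded peak of either replicate.

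Signal ranked shared peaks alike in both replicates. Over 1149 mutually paired peaks Spearman's rho was 0.758 and Pearson's r on log2 signal 0.830 (permutation p = 1e-05 for each, the smallest that 100000 random pairings allow), and without the 2 peaks farthest from the median they were 0.757 and 0.826. The correlation is across peaks, which are not independent replicates. Paired summits lay a median of 18 bp apart. Over the ranked lists, most of whose peaks did not pass the threshold, rho was 0.374.

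Summits were concentrated at promoters and nearly absent from coding sequence. Of 2883 summits, 1275 (44.2%) lay within 500 bp of an annotated transcript start, against 13.5% ± 0.795 (SD over 1000 circular shifts). Introns held 38.0% (40.01% in shifted sets), intergenic sequence 15.6% (27.7%), coding sequence 1.04% (13.7%) and 3' UTRs 0.659% (4.38%). The promoter excess and the deficits in coding sequence, 3' UTRs and intergenic sequence were past every shift (two-sided permutation p = 0.002, the smallest the shifts allow), whereas introns did not differ (permutation p = 0.124) and neither did 5' UTRs, with 0.451% against 0.777% (permutation p = 0.0579). Ranked peaks below the threshold had a promoter share of 14.0%.

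**Figure D2:**
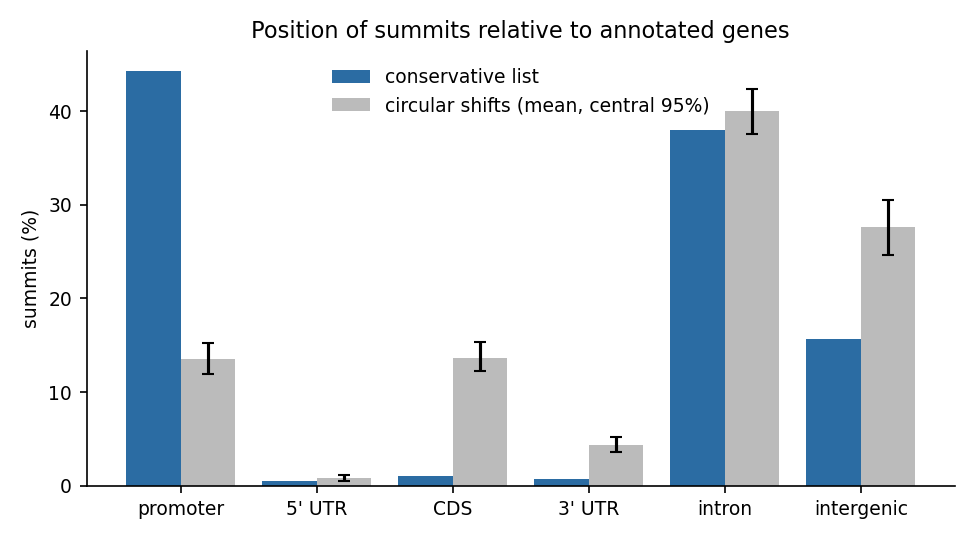
Share of summits (%) in each class of annotated sequence for the conservative list (blue) and for circularly shifted summits (grey, mean with the central 95% of 1000 shifts). Promoters hold 44.2% of summits against 13.5% in shifted sets.

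The X chromosome and the large autosomal arms were bound at similar density, and chromosome 4 had no peak in the conservative list. X held 498 peaks (21.2 per Mb) and 2L, 2R, 3L and 3R together 2384 (21.9 per Mb), a ratio of 0.967 (exact binomial 95% interval 0.876 to 1.07, two-sided exact p = 0.511). Chromosome 4 held 0 peaks where 29.5 would match the density of the arms (exact binomial p = 4.18e-13), a comparison chosen after its values were seen. The ranked list was sparse there too, with 60.8 peaks per Mb on chromosome 4 and 1078 on the arms. It held 1 chromosome 4 peak at or above the authors' threshold score (1319101 to 1319396, signal 53.8) that the conservative list lacks. Replicate 1 had 0 thresholded peaks on chromosome 4 and replicate 2 had 3.

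Ribosomal protein genes were the most enriched of the 15 fixed gene lists. Of 92 cytosolic ribosomal protein genes 62 (67.4%) had a summit in their domain, against 10.7 in random lists matched on domain length, a 5.81-fold excess (permutation p = 0.0002, the smallest the draws allow, adjusted p = 0.001). The strongest peaks were at the promoters of RpS27 (FBgn0039300, 3R 25247428 to 25247613, signal 297), RpL32 (signal 255) and RpL7 (signal 250). Chemosensory receptor genes, which encode odorant, gustatory and ionotropic receptors, were depleted, with 2 of 179 (Or88a and Ir94c) against 25.3 expected (permutation p = 0.0002, adjusted p = 0.001). Both calls held in each replicate's own list.

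The list of Notch pathway and E(spl) complex genes was the other one past the threshold. Summits were found at 13 of 23 genes against 4.66 expected, 2.79-fold (permutation p = 0.0002, adjusted p = 0.001). The strongest were at gro, which encodes the corepressor Groucho (FBgn0001139, 3R 26042438 to 26042579, promoter, signal 271), in an intron of N, the receptor Notch (FBgn0004647, X 3162454 to 3162582, signal 220), and at E(spl)mdelta-HLH (promoter, signal 139). Split after the values were seen, the 11 E(spl) complex members had a summit at 6 against 0.924 expected (permutation p = 0.0002, the smallest the draws allow) and the 12 other Notch genes at 7 against 3.76 (permutation p = 0.072), and the difference between the parts was not tested. The random lists were not matched for genes that lie side by side. The bound members were E(spl)mdelta-HLH, E(spl)mbeta-HLH, E(spl)malpha-BFM, E(spl)m2-BFM, E(spl)m3-HLH and E(spl)m7-HLH, and E(spl)m4-BFM, E(spl)m5-HLH, E(spl)m6-BFM, E(spl)m8-HLH and E(spl)mgamma-HLH had 0. The call did not hold in the list of either replicate alone (1.68-fold, adjusted permutation p = 0.654 in replicate 1, and 2.47-fold, 0.068 in replicate 2), in the stronger peaks of the list (2.41-fold, 0.142) or with summits within 1 kb of a transcript start (2.00-fold, 0.422).

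The remaining 12 lists did not pass the threshold, with adjusted permutation p from 0.115 to 0.667. Genes of Wnt, BMP, EGFR and Hedgehog signalling had summits at 16 of 29 (9.997 expected, adjusted permutation p = 0.115), with the strongest at fz (signal 283), aos (249) and aop (233). This list passed with the other thresholded list (adjusted permutation p = 0.00975) and with replicate 1 alone (0.01). It also passed with summits given to the nearest transcript start (adjusted permutation p = 0.001) and without matching on length (0.00075). It did not pass with replicate 2 alone (adjusted permutation p = 0.193) or in the stronger peaks (0.214). Within 1 kb of a start 7 genes had a summit against 6.17 expected (adjusted permutation p = 1). Germline and maternal genes had 7 of 15 (3.28 expected), led by bgcn (148), bcd (104) and swa (95.9). Sensory organ precursor and proneural genes had 8 of 20 against 5.36 expected (adjusted permutation p = 0.463), led by sens-2, chn (194) and numb (178). Hox and homeotic genes had 7 of 12 (4.71 expected), led by Dll (204), Ubx (139) and hth (109). The Hox list passed with summits given to the nearest transcript start (adjusted permutation p = 0.024) and without matching on length (0.0132), but had 4 against 3.72 expected in replicate 1 alone, 4 against 3.37 in replicate 2 alone and 1 against 2.73 within 1 kb of a start. Glial genes had 8 of 18 (5.21 expected), led by moody (290), loco (116) and Gs2 (103), and gut and endoderm genes 6 of 14 (3.77 expected), led by bowl (233), cad (95.2) and fkh (88.6). Epidermis, cuticle and trachea genes had 9 of 20 (6.69 expected), led by grh (199), rib (198) and sty (83.5), and mesoderm and muscle genes 9 of 26 (7.59 expected), led by Mef2 (259), kirre (204) and tin (186). Differentiated and sensory neuron genes had 7 of 24 (8.54 expected), led by elav (226), cpo (184) and ct (72.9). Neuroblast genes had 4 of 24 (6.54 expected), led by grh, pros (140) and SoxN (84.6), hemocyte and fat body genes 3 of 16 (4.65 expected), at ush (149), glec (81.9) and srp (62.7), and segmentation genes 3 of 25 (5.42 expected), at bcd, cad and inv (61.3). With summits given to the nearest transcript start the segmentation list had 10 against 4.38 expected and passed (adjusted permutation p = 0.0365), and without matching on length the germline, glial and epidermis lists passed (0.0416, 0.0356 and 0.025).

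**Figure D3:**
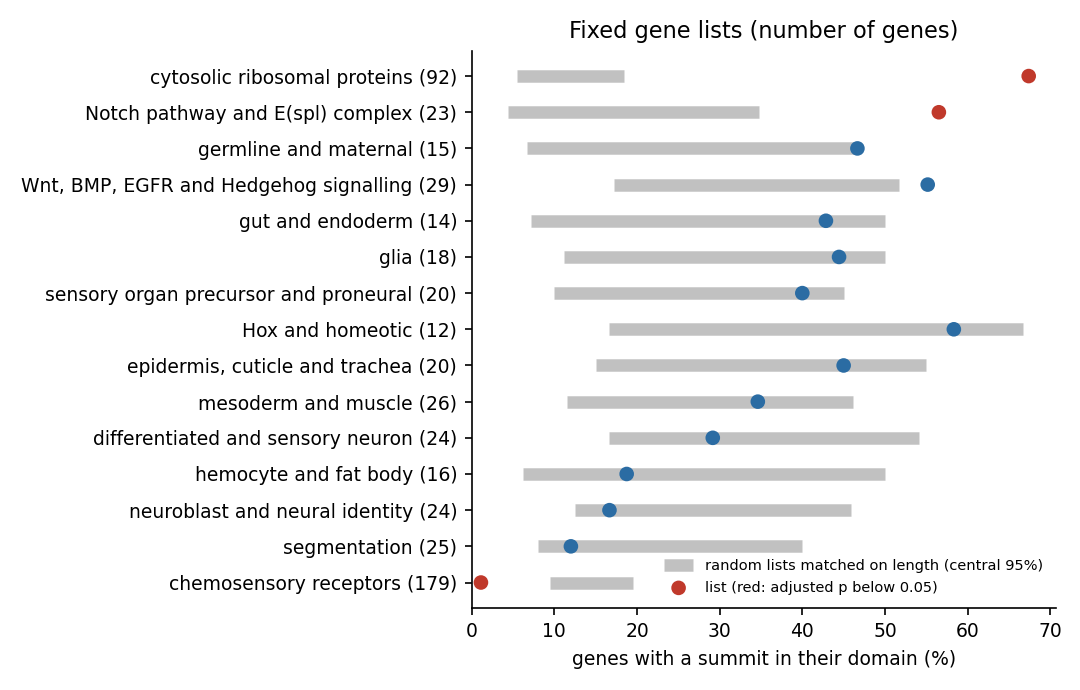
Share of genes (%) with a summit in the gene body or 2 kb upstream for each fixed list, with the number of genes in parentheses; grey bars span the central 95% of 10000 random lists matched on length, and red points have an adjusted p under 0.05. Ribosomal protein genes stand at 67.4% and chemosensory receptor genes at 1.12%.

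The Senseless core hexamer AAATCA was more frequent at summits than beside them. It occurred within 50 bp of 517 of 2883 summits (17.9%) and in 303 flanking windows of the same width (10.5%), a ratio of 1.71, with 466 peaks holding it only at the summit and 252 only at the flank (two-sided exact McNemar p = 1.16e-15). Among ranked peaks below the threshold 9.68% held it (two-sided Fisher's exact p = 6.32e-41). That comparison was not matched for position or base composition. Of the peaks below the threshold 18.6% lay in coding sequence, against 1.04% of the conservative list. The difference between summit and flank was present in the lists of both replicates, at 5.26 percentage points in replicate 1 and 6.72 in replicate 2. Summits were also rich in A and T, and the other 29 hexamers made of the same bases had ratios of up to 1.68 (AAACTA) with a median of 1.29. Peaks with AAATCA had a median signal of 77.6 and those without it 78.9 (two-sided permutation p = 0.568).

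Of 14 further preset motifs 6 passed the threshold, 4 of them higher at summits. The test did not allow for base composition. In the strongest 1000 peaks GC was 33.8% at summits and 43.4% at flanks, and in the rest 38.7% and 42.6%. The same test called 316 hexamers more and 484 less frequent at summits. Whether the calls below reflect binding of the named factors or base composition was therefore not tested. GATAAG, the site of GATA factors, stood at 7.84% against 5.20% (adjusted exact McNemar p = 0.000177), TATCGATA, the site of DREF, at 1.25% against 0.277% (0.000177), the homeodomain site TAATTA at 8.53% against 6.42% (0.00743) and the shuffled control CATAAA at 13.1% against 10.5% (0.00743). GAGAG, bound by GAGA factor, was lower at summits, 11.7% against 15.6% (adjusted exact McNemar p = 0.000177), as was GTGGGAA, the site of Su(H), at 0.902% against 1.84% (0.00743). The second shuffled control, TACAAA, stood at 12.7% against 10.8% (0.0631), and CAGGTA, CAGCTG, CAGATG, CATATG, CACCTG, CACGTG and AACCGGTT did not pass. Several of these calls depended on the settings: motif GAGAG did not pass with flanks 1000 bp away (adjusted exact McNemar p = 0.646) and motif GATAAG and motif TAATTA not within 51 bp (0.13 and 0.0527). The call for motif GTGGGAA was lost in the other thresholded list (adjusted exact McNemar p = 0.0705), with either replicate alone (0.56 in replicate 1 and 0.875 in replicate 2, where the sign turned), in the stronger peaks, away from promoters and with each other window or flank. The control motif TACAAA passed with flanks 1000 bp away (adjusted exact McNemar p = 1.78e-05), where the control motif CATAAA did not (0.0659). The motif CACCTG, lower at summits, passed in the other thresholded list (adjusted exact McNemar p = 0.0315), in replicate 1 alone (0.0177) and with each other window or flank distance, but not in replicate 2 alone (0.298) or with the flank on the other side (0.519). In the stronger peaks motif CAGATG and motif CAGCTG passed (adjusted exact McNemar p = 0.0248 and 0.0276). Among peaks more than 500 bp from a transcript start, TATCGATA was equally frequent at summits and flanks.

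Across all hexamers, with reverse complements merged, 316 were more and 484 less frequent at summits (adjusted exact McNemar p under 0.05). The leading hexamers were TTAAAA (27.3% against 15.3%), ATTTAA (24.1% against 12.7%) and AAATAT (27.7% against 15.7%). AAATCA ranked 13th among those enriched, and the 12 ahead of it held no G or C. It ranked 34 in the list of replicate 2 and lower still in that of replicate 1.

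**Figure D4:**
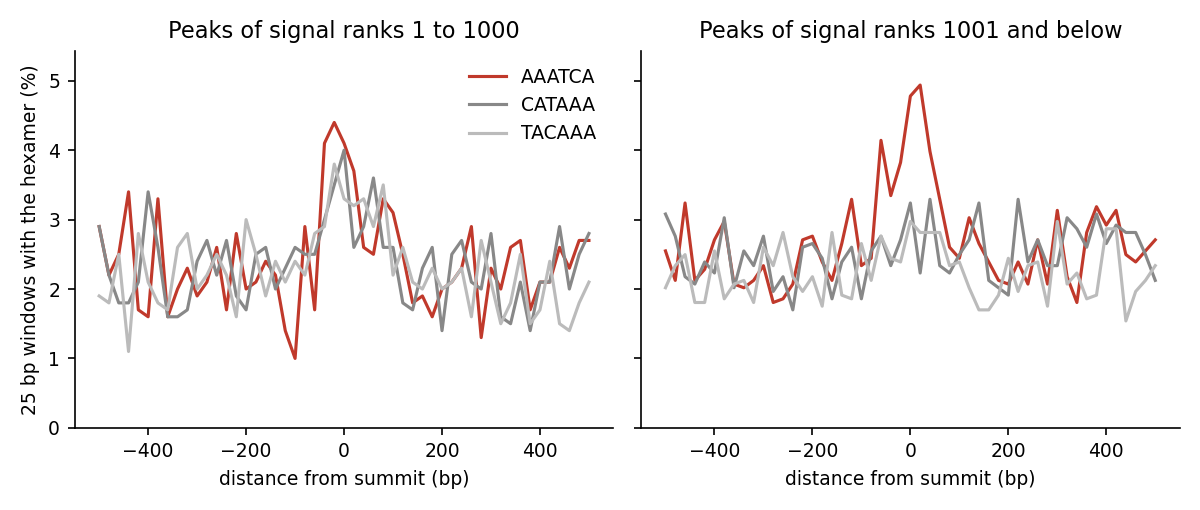
Share (%) of 25 bp windows holding AAATCA (red) or the shuffled controls CATAAA and TACAAA (greys) by distance from the summit in bp, for the 1000 peaks of highest signal and for the rest. At the summit of the stronger peaks AAATCA stands at 4.1% and CATAAA at 4.0%, and in the weaker peaks at 4.78% and 3.24%.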

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

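The ranked list that compared the replicates held 87 peaks at or above the authors' threshold score that the conservative list lacks, a signal in data outside the comparisons above. Of these, 75 lay on assembled chromosomes, with 36 on 3R and 24 on 2L, and their median signal was 78.5, against 78.6 in the conservative list. The strongest had a signal of 849, the fourth highest of all ranked peaks, at 3R 11760931 to 11761153, 958 bp from the nearest start of Lk6, and the next a signal of 793 at 2L 480967 to 481210 near cbt. Others lay near larp (415), Alh (308), tara (283), trx (258), RpL13A (197) and Hsp70Ba (152). This comparison was chosen, and these genes were named, after the values were seen. The thresholded lists derived from a further file that was not used here, and whether it removed these peaks was not tested.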

How the results depend on the processing

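Chosen after seeing the data were the alternatives without peaks of signal under 20, with only peaks of full width, without peaks at the sens-2 domain and with the flank on the other side. Over all alternatives, 79 values of the main results kept their direction and side of the threshold, 5 moved, 4 changed direction and 1 newly passed. Those that kept both included every value for replicate overlap, signal correlation, promoter share and the AAATCA difference. The X to autosome peak density ratio, near 1 throughout, was 1.11 in the stronger peaks of the list and ranged from 0.975 to 1.05 when a replicate was left out. The number of gene lists enriched or depleted rose from 3 to 6 with summits given to the nearest transcript start and to 8 without matching on length, and fell to 2 with replicate 2 alone, in the stronger peaks and within 1 kb of a start. With replicate 1 alone it was 3, with the Wnt, BMP, EGFR and Hedgehog signalling list in place of the Notch list. Enriched hexamers numbered 184 with a window of 51 bp and 199 to 320 with a replicate left out, and 2 preset motifs passed among peaks away from promoters. The difference in signal of peaks with and without AAATCA was 2.34 in the other thresholded list, 0.598 for peaks of full width and -4.54 with the wider window (permutation p = 0.0272). Values that changed sign without passing the threshold, in percentage points from expectation, were for the gene lists segmentation 0.824 in the other thresholded list, epidermis, cuticle and trachea -1.19 in the stronger peaks, Hox and homeotic -14.5 within 1 kb of a start (41.5 and passing by nearest start), differentiated and sensory neuron 3.20, neuroblast and neural identity 15.1 and hemocyte and fat body 0.969 by nearest start, and neuron 11.2 and hemocyte 0.951 without matching. Segmentation by nearest start was at 22.5 and passed (adjusted permutation p = 0.0365). With a replicate left out, epidermis ranged from -8.60 to 3.82 and gut and endoderm from -3.86 to 1.29, motif CATATG from 0 to 1.16, motif GTGGGAA from -0.306 to 0.122 and motif AACCGGTT from -0.122 to 0.0510. Further sign changes, none past the threshold, were motif CAGCTG 0.277 and CATATG 0.416 with the wider window, motif CAGGTA 0.435 and CATATG 0.435 away from promoters, and CATATG 0.555 and AACCGGTT 0.0347 with the other flank. Over single lists, motifs and named genes, 735 values kept their direction and side, 103 moved, 20 changed direction, 26 newly passed and 23 no longer passed. The cause was not tested. Leaving out a replicate was not possible for overlap and correlation, which need both, and the lists give no read depth.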

Other observations

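For the 3 patterns weighed, some tests were chosen only after their own result was seen. These were the percentile of the sens-2 window in the list across replicates, the windows centred on summits and the windows as dense as that at sens-2. Both tests of base composition and GC over about 800 bp were also chosen so. The housekeeping groups were chosen after the ribosomal protein result was seen, but before their own. The design has 1 group, so no biological explanation that rests on a difference between groups was tested.

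Other groups of housekeeping genes, chosen after the ribosomal protein result was seen, had a summit within 1 kb of a transcript start in 34 of 220 genes (15.5%), against 23.2 expected from matched lists (1.46-fold, permutation p = 0.0264) and 13.0% of all protein-coding genes. By group, such a summit was found for 14 of 73 mitochondrial ribosomal protein genes (19.2%, 2.57-fold over matched lists, adjusted permutation p = 0.007), 9 of 44 translation initiation factors, 4 of 22 vacuolar ATPase subunits, 5 of 33 aminoacyl-tRNA synthetases and 2 of 48 proteasome subunits, and the last 4 groups did not pass the threshold. In a comparison also chosen after seeing the data, around AAATCA sites at summits differed from sites at flanks in the bases downstream of the core, with C at the fourth base after it in 24.4% against 15.4% (adjusted Fisher's exact p = 0.00402), G at the third in 26.1% against 18.4% (0.0228) and with less C at the second, 11.0% against 20.2% (0.00126), and less G at the fourth, 16.04% against 23.7% (0.0204).

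The main list held 63 peaks of signal under 20, all of which had another listed summit within 300 bp (median 203 bp), against 3.48% of the other peaks.

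Peak signal was raised over a wide region around sens-2, with a median of 28.2 for below-threshold peaks in the 60 kb centred on the gene, percentile 99.98 of 12640 windows, and percentile 99.94 in each replicate's own ranked list. Extra copies of the region in the tagged line and broad weak binding would both give such values and cannot be told apart by them, and windows away from sens-2 reached 26.9 (3L 17960001 to 18020000), with 5 windows rising at least 0.75 times as far above the genome median. In the replicates' own lists windows elsewhere reached 18.7 and 14.9, above the 16.8 and 13.8 at sens-2, with 48 and 37 windows rising that far. A rule written beforehand took a high percentile in both replicates' own lists as speaking for extra copies, and its bound was passed. It was set aside afterwards, because windows elsewhere rose as far. Dense binding that lifts the peaks nearby stays open as well. The windows of the 5 other genes with most summits had medians of at most 19.2, also when centred on their summits (19.2). None rose 0.75 times as far above the genome median, which a rule written beforehand took as speaking against dense binding. That rule was set aside afterwards, because the windows centred on summits held 5 to 13 summits and the one at sens-2 held 15. Only 1 other locus was as dense (3L 590001 to 670000, with up to 16 summits in 60 kb), and its highest median was 19.5.

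The strongest summits were rich in A and T, and AAATCA had the lowest p of all enriched hexamers only below the strongest 1000 peaks. GC content at the summit was 33.8% in the 1000 strongest peaks and 38.7% in the rest, while over about 800 bp it differed by 0.0726 percentage points (permutation p = 0.679), which argues against a GC bias on the longest fragments, while a bias on shorter ones was not tested. Away from promoters the strongest summits were also lower, at -4.24 percentage points (permutation p = 1e-05, the smallest possible), which argues against promoter sequence as the only cause. At promoters the difference was larger, at -6.07 percentage points, so a part played by promoter sequence is not excluded. The ratios could not tell whether base composition alone gives the AAATCA excess. AAATCA had the highest ratio among hexamers of its bases in 37.65% of 2000 resamples of all peaks. For the peaks below the strongest 1000 it did so in 87.1%. There its lead over the next hexamer, AATCAA, had a bootstrap 95% interval of 0.0305 to 0.630. AATCAA overlaps AAATCA within AAATCAA, so their counts are not independent. In the strongest 1000 the ratio of AAATCA, 1.5, equalled the median of the others. In the rest it was 1.82 against a median of 1.22 and at most 1.49 for the others, while CACTGA had 2.05 and ATAAGA 1.99. After the core, summit sites had more G at the third base (26.1% against 18.4% at flanks) and more C at the fourth (24.4% against 15.4%). A gain in A and T alone would not give these rises, though less C at the second and less G at the fourth go with it. The rises argue against base composition as the only difference between the sites.

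Ribosomal protein genes stood apart from other broadly expressed genes. The other housekeeping genes had a summit near a start in 15.5% (1.46-fold over matched lists). Ribosomal protein genes had one in 67.4% (7.29-fold), and the shares differed (Fisher's exact p = 7.77e-19). Of the ribosomal protein genes with a summit, 95.2% were the nearest gene to one. This share cannot decide whether the summits belong to neighbouring genes. The genes were selected for a summit in their body or 2 kb upstream, which favours being nearest, and no share was computed for other genes. Binding through the exact hexamer AAATCA is argued against by its share of 3.33% (2 of 60) at the promoter summits of ribosomal protein genes. This was below the 18.7% at other promoter summits (Fisher's exact p = 0.000884). Base composition was not matched in this comparison, and variants of the hexamer were not counted. A dependence of the signal on very high transcription, or unspecific precipitation at such promoters, stays open because no expression values or control library were used here.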
